A study of Macaca fascicularis with 48 samples.

How the data were processed

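Bulk RNA-seq of cerebral cortex was analysed from 24 cynomolgus monkeys (Macaca fascicularis). Per the labels, each animal received a single intravenous dose of 200 mg/kg of either hPara.09, an antibody that activates TREM2, or anti-gD, the isotype control, and brain was taken on day 4 or day 28. The agent label of the treated animals reads Para09.v2, while the series text names hPara.09, and the latter name is used here. There were 6 animals in each of the 4 groups and 2 libraries from each animal, 48 libraries in all, made from different frontal cortex punches. RNA was extracted with a lipid tissue column kit and DNase digestion, per the labels' protocols.

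Each library's deposited file gave, for 28623 Ensembl gene IDs, a whole-number exonic read count, a gene width and an RPKM value, per the file headers. GSNAP is the only tool named in the submitters' processing notes, and its version, the genome build and the annotation are not given in the sources used here. Strand handling and the treatment of reads shared between near-identical genes are not given either, so genes that overlap or have close copies are uncertain. The deposited RPKM values had been divided by one whole number of reads per library, recovered from the count, width and RPKM of each gene, and this number was larger than the sum of the counts. The sum of the counts as a percent of it is called the exonic share here, and it ranged from 57.09% to 64.97% over the libraries. Which reads the divisor holds is not stated, so the name is a label and not a measured exonic fraction. RPKM was used for nothing else, and all tests were run on the deposited counts.

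The total count per library ranged from 12137146 to 32118950, with a median of 20918721. The counts of both libraries of an animal were summed for the comparisons between groups, which gave 32116548 to 55236819 counts per animal. No files were identical. A chi-square of the counts of an animal's libraries, over genes with at least 20 reads, was 9.007 to 115.6 per degree of freedom, far above sampling noise, so the libraries were treated as separate samples of 1 animal. The animal was the replicate in all main tests. An alternative comparison of the libraries of an animal, with no replicate block, left the animal out of the model.

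None of the 28623 IDs was paired with a name, because the files hold IDs only and the table of gene names used here holds no Ensembl IDs (0 matched). The 25 gene lists fixed before the data were examined (513 genes, among them microglia, cell cycle, interferon, cytokine and other cell type lists) and the panel of named microglial genes were therefore not analysed here. Genes are given by ID, and no name or function is attached to any of them.

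The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, the default low-count filter, robust dispersion estimates and 1 mean per group over all 24 animals. The filter kept 16721 genes, which hold 99.98% of the counts, and the common biological coefficient of variation was 24.3%. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Contrasts were hPara.09 against anti-gD on each day, the difference of these contrasts between days, and day 28 against day 4 in the anti-gD animals. Standard errors are the log2 fold change divided by the square root of F, and intervals are at 95%. Libraries with title numbers 25 to 48 were compared with those numbered 1 to 24 with the animal as a block, since every animal has 1 library in each set. The labels do not say which punch or site a set holds. Fixed before the data were examined were the groups, the tests, the rule for named genes and most alternatives. That rule took the genes past the threshold with the largest fold change and a mean of at least 1 CPM. It asked for a symbol, which no gene has, so it was used without one for the library sets, with at most 2 IDs each way. Every other gene named was chosen after its values were seen.

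Variance components between animals and between the libraries of an animal came from a nested analysis of log2 CPM with a prior count of 2. Library measures were compared between groups of 6 with exact two-sided permutation tests, and between library sets with 100000 sign flips. The scripts were tested on simulated counts with 200 changed genes drawn from the real means and library sizes. At day 4, with 16625 genes, 39.7% of genes changed 1.5-fold, 74.9% of those changed 2-fold and 93.1% of those changed 4-fold were recovered. At day 28, with 16632 genes, the shares were 42.1%, 71.6% and 91.6%. For the control days, with 16635 genes, they were 41.5%, 75.2% and 95.8%, and for the library sets, with 15842 genes, 80.0%, 89.9% and 95.5%. False calls were 3.34% to 4.99% of calls. The shares hold for 200 changed genes at once. With fewer changed genes the adjustment is harder on each, so smaller shares would be recovered, and this was not simulated. Simulated genes vary independently, which real genes do not. For the library sets, each library was drawn on its own, with no animal effect shared by a pair. The dispersions came from the summed counts, so these shares do not test the paired design. In the nested analysis, a simulated share between animals of 50% was estimated as a median of 49.8%.

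Alternatives were RLE and upper-quartile factors, no filter and a filter of at least 1 CPM in at least 12 animals, DESeq2 1.42.0, limma 3.58.1 (voom with duplicateCorrelation) on the 48 libraries, only the groups compared, either library set alone, and each animal left out. Chosen after seeing the data were the exonic share as a covariate, the library set as a term, leaving out the libraries with title numbers 29 and 40, the newer quasi-likelihood version of edgeR, the thinning of libraries to equal totals, leaving out the 13 most abundant IDs, and contrasts pooled over days or over antibodies.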

Results

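The series text names TREM2 agonist treatment of cynomolgus monkeys as its subject. TREM2 is a receptor that microglia, the resident macrophages of the brain, carry on their surface. Cerebral cortex was profiled by bulk RNA-seq in 24 animals given a single dose of 200 mg/kg of hPara.09 or of the isotype control anti-gD, with 6 animals for each antibody at day 4 and 6 at day 28. Both libraries of each animal, made from different frontal cortex punches, were counted. Libraries held 12137146 to 24247955 counts in the anti-gD day 4 group and 14028312 to 32118950 in the hPara.09 day 4 group. They held 13656102 to 25998239 in the anti-gD day 28 group and 16612369 to 26339262 in the hPara.09 day 28 group. Genes are given by Ensembl ID, since the files pair no ID with a name, and the levels of microglial and other named genes were not analysed here.

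The first comparison asked which transcripts differed between hPara.09 and anti-gD 4 days after the dose. None of the 16721 genes tested passed the threshold in edgeR's quasi-likelihood test (smallest adjusted p = 0.629). The 95% interval of the fold change lay within 2-fold either way for 87.8% of genes, and for 98.0% of the 9565 genes with a mean of at least 10 CPM. It lay within 1.5-fold for 68.3% of genes. Groups did not overlap for 16 genes, 0.0957% of those tested, where chance gives 0.216%. The gene with the smallest p, singled out after its values were seen, was ENSMFAG00000000864. Its level was 13.81 ± 4.66 CPM (SD, n = 6) with hPara.09 and 6.917 ± 1.03 CPM (SD, n = 6) with anti-gD, and all 6 hPara.09 animals lay above the anti-gD mean. Its log2 fold change was 1.00 with a standard error of 0.199, and its adjusted p of 0.629 in edgeR did not pass. At day 28 the same gene was at 9.451 to 15.44 CPM with hPara.09 and 8.059 to 17.19 CPM with anti-gD (log2 fold change -0.06, standard error 0.196, adjusted p = 0.978). At an unadjusted p under 0.05 there were 433 genes, 223 higher and 210 lower, where an even spread of p would give 836. This count was 985 with title numbers 1 to 24, 298 with title numbers 25 to 48, and 351 to 605 with 1 animal of these groups left out. DESeq2 called 1 gene and limma voom called 0. The gene that DESeq2 called was ENSMFAG00000000864 (adjusted p = 0.0179), which edgeR also called in the libraries with title numbers 1 to 24 alone (adjusted p = 0.0275). Over all alternatives its adjusted p ranged from 0.0179 to 1. Leaving out animal 11 of the hPara.09 day 4 group gave 1 called gene, ENSMFAG00000000864 (adjusted p = 0.0276). Leaving out animal 12 gave 1 other gene, with ENSMFAG00000000864 at an adjusted p of 0.676.

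The same question at day 28 gave the same count. None of 16721 genes passed in edgeR's test (smallest adjusted p = 0.644), and the 95% interval lay within 2-fold either way for 86.8% of genes and for 97.7% of those with at least 10 CPM. It lay within 1.5-fold for 66.2% of genes. Groups did not overlap for 29 genes, 0.173%, where chance gives 0.216%. The gene with the smallest p, again singled out after its values were seen, was ENSMFAG00000034441. It stood at 92.07 ± 12.3 CPM (SD, n = 6) with hPara.09 and 66.07 ± 4.85 CPM (SD, n = 6) with anti-gD, with all 6 hPara.09 animals above the anti-gD mean. The log2 fold change was 0.48 with a standard error of 0.0956 and an edgeR adjusted p of 0.644. At day 4 the same gene was at 56.57 to 80.58 CPM with hPara.09 and 63.72 to 81.99 CPM with anti-gD (log2 fold change -0.05, standard error 0.0955, adjusted p = 1). At an unadjusted p under 0.05 there were 809 genes, 529 higher and 280 lower, against 836 for an even spread. This count was 1838 with title numbers 1 to 24, 518 with title numbers 25 to 48, and between 507 (without animal 21) and 1438 (without animal 19) with 1 animal of these groups left out. DESeq2 called 2 genes, ENSMFAG00000034441 and ENSMFAG00000042448, and limma voom called 0.

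**Figure D1:**
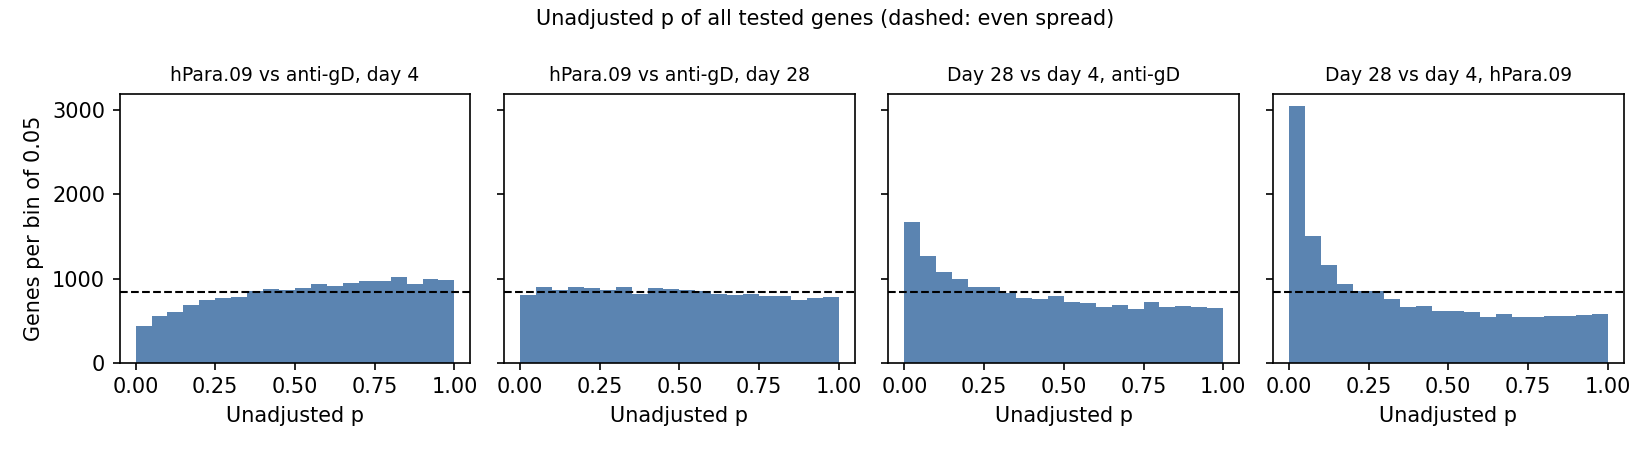
Number of genes (y axis) in each bin of 0.05 of the unadjusted p (x axis) from edgeR's quasi-likelihood test for 4 comparisons of 6 animals against 6; the dashed line is an even spread over the 16721 genes. The first bin holds 433 genes for hPara.09 against anti-gD at day 4, 809 at day 28, 1677 for day 28 against day 4 in anti-gD animals and 3050 in hPara.09 animals.

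Whether the antibody difference itself changed between the days was tested directly. No gene passed in edgeR's main test (smallest adjusted p = 0.214), with 716 genes at an unadjusted p under 0.05 (1718 with title numbers 1 to 24, 398 with title numbers 25 to 48, and 536 to 977 with 1 animal left out). DESeq2 called 1 gene, ENSMFAG00000039796 (adjusted p = 0.00381), which the newer quasi-likelihood version of edgeR, tried after seeing the data, also called (adjusted p = 0.0368). Limma voom called 1 other, ENSMFAG00000011493, without and with the library set as a term (adjusted p = 0.00242 and 0.00534), the term being added after seeing the data. Across the 16721 genes, the log2 fold changes of day 4 and day 28 had a Pearson r of -0.0848 and a Spearman rho of -0.0566, and 49.0% of genes had the same sign. The days use separate control animals, and genes are not independent replicates.

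One gene stood out on both days and was singled out after its values were seen. ENSMFAG00000046527 was at 3.989 to 10.31 CPM in 7 of the 12 hPara.09 animals, 4 at day 4 and 3 at day 28, and at most 0.4724 CPM in the other 5 and in all 12 anti-gD animals. Its p ranked 5 among all genes at day 4 and 6 at day 28. It passed the threshold on neither day in edgeR, nor with both days pooled, a contrast added after seeing the data (log2 fold change 4.34, standard error 0.756, adjusted p = 0.133, between 5.21e-06 with DESeq2 and 1 over the alternatives). DESeq2 called it with the days pooled, and edgeR did so when animal 8 of the hPara.09 day 4 group or animal 22 of the hPara.09 day 28 group, both at low level (0.05507 and 0.1853 CPM), was left out.

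**Figure D2:**
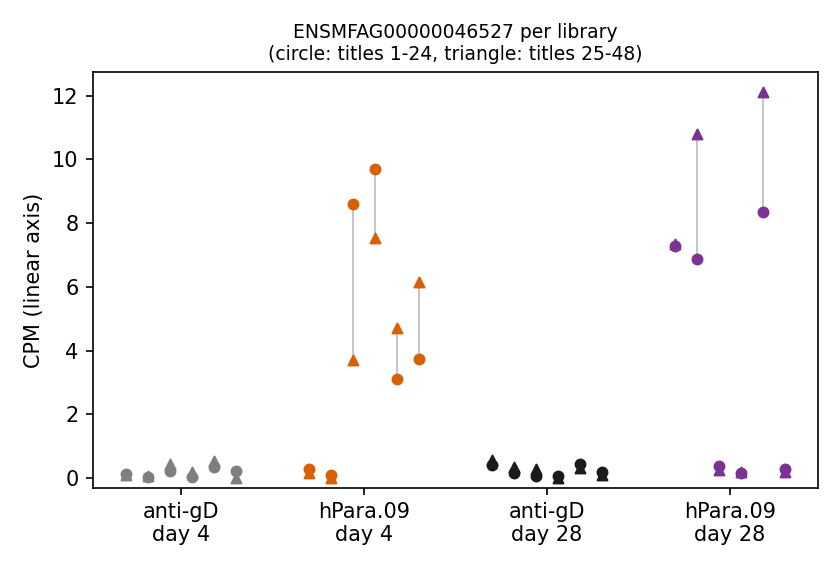
Level of ENSMFAG00000046527 in CPM (y axis, linear) in both libraries of each animal (joined by a line; circle, title numbers 1 to 24; triangle, 25 to 48) in the 4 groups of 6 animals (x axis). In 7 hPara.09 animals both libraries lie at 3.097 CPM or higher, and in all other animals both lie at 0.5533 CPM or lower.

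Day 28 was compared with day 4 in the anti-gD animals as a measure of what changes without the agonist. No gene passed in edgeR (smallest adjusted p = 0.0847), although 1677 genes had an unadjusted p under 0.05, 882 higher and 795 lower at day 28. This count was 2908 with title numbers 1 to 24, 1001 with title numbers 25 to 48, and 1128 to 2446 with 1 animal of these groups left out. The gene with the smallest p, chosen after its values were seen, was ENSMFAG00000036375, at 8.345 ± 2.11 CPM (SD, n = 6) at day 28 and 4.089 ± 0.654 CPM (SD, n = 6) at day 4. Its log2 fold change was 1.03 with a standard error of 0.177 and an edgeR adjusted p of 0.0847. In hPara.09 animals the same gene was at 6.001 to 8.099 CPM at day 28 and 4.472 to 8.561 CPM at day 4 (log2 fold change 0.04, standard error 0.174, adjusted p = 0.93). Groups did not overlap for 57 genes, 0.341% of those tested, where chance gives 0.216%. DESeq2 called 57 genes and limma voom called 0. The libraries with title numbers 1 to 24 alone gave 16 genes in edgeR and those numbered 25 to 48 gave 0. Leaving out animal 17 of the anti-gD day 28 group gave 3 genes, and leaving out animal 6 of the anti-gD day 4 group gave 1.

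The exonic share was compared between the groups. It was 62.45% ± 0.85 (SD, n = 6) in anti-gD and 61.88% ± 1.22 (SD, n = 6) in hPara.09 animals at day 4, and 60.54% ± 2.13 (SD, n = 6) and 59.14% ± 1.29 (SD, n = 6) at day 28. The day difference in hPara.09 animals was -2.738 percentage points (exact two-sided permutation p = 0.00866, adjusted p = 0.1385 over 16 tests of library measures), and in anti-gD animals -1.905 points (exact permutation p = 0.0714, adjusted p = 0.571). Between antibodies the difference was -0.5667 points at day 4 and -1.4 points at day 28 (exact permutation p = 0.396 and 0.204). After adjustment, neither the exonic share, depth, the share of the 13 most abundant IDs nor the number of genes detected passed in any of the 4 comparisons.

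**Figure D3:**
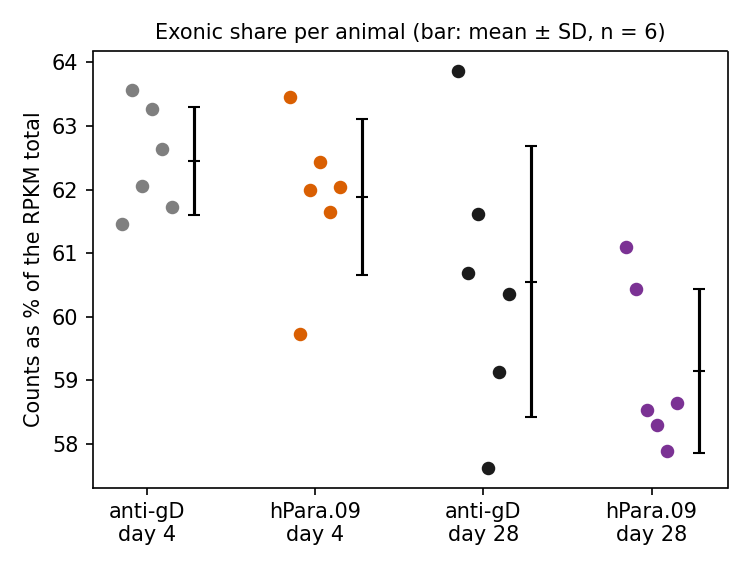
Exonic share of each animal, the summed counts as a percent of the total behind the deposited RPKM (y axis, which does not start at 0), in the 4 groups (x axis; points, 6 animals each; bars, mean ± SD). The means are 62.45% and 61.88% at day 4 and 60.54% and 59.14% at day 28.

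The series text states that 2 punches were taken to see how much expression varies between brain samples. The libraries with title numbers 25 to 48 differed from those numbered 1 to 24 of the same animals in 9359 of 15853 genes (59%), 4885 higher and 4474 lower, in edgeR's test with the animal as a block. Most of these differences were small. The median absolute log2 fold change of the called genes was 0.294, with 1176 past 1.5-fold and 121 past 2-fold. In 548 genes the difference had the same direction in all 24 animals, 432 of them higher and 116 lower. The genes with the largest rise were ENSMFAG00000041678 (log2 fold change 1.77, standard error 0.438, edgeR adjusted p = 0.00143, higher in 20 of 24 animals) and ENSMFAG00000039785 (1.64, standard error 0.153, adjusted p = 2.63e-09, higher in 23 of 24). Those with the largest fall were ENSMFAG00000042382 (-1.43, standard error 0.212, adjusted p = 2.5e-06, higher in 2 of 24) and ENSMFAG00000040157 (-1.36, standard error 0.148, adjusted p = 1.73e-08, higher in 1 of 24). The sets also differed in depth, by a mean of -2240948 counts (sign-flip permutation p = 0.012, adjusted p = 0.024 over 4 measures), and in genes detected, by -259.8 (permutation p = 0.0012, adjusted p = 0.0048), lower in the higher-numbered set in 16 and 19 of 24 animals.

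Between animals of a group lay a median of 31.0% of the variance of log2 CPM that was not due to group (jackknife standard error over animals 4.21), and the rest lay between the libraries of an animal. That rest mixes differences between punches with those of library preparation and sequencing. They cannot be told apart, since an animal's libraries came from different punches. The share between animals was over 50% for 27.2% of the 15853 genes. With the mean of each library set removed, a step chosen after seeing the data, the median share was 46.8%. The library most like a given library came from the same animal for 31 of 48 libraries, and for 45 of 48 with set means removed, where chance gives 2.13%. The limma consensus correlation within an animal was 0.313, and 0.477 with the set as a term.

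**Figure D4:**
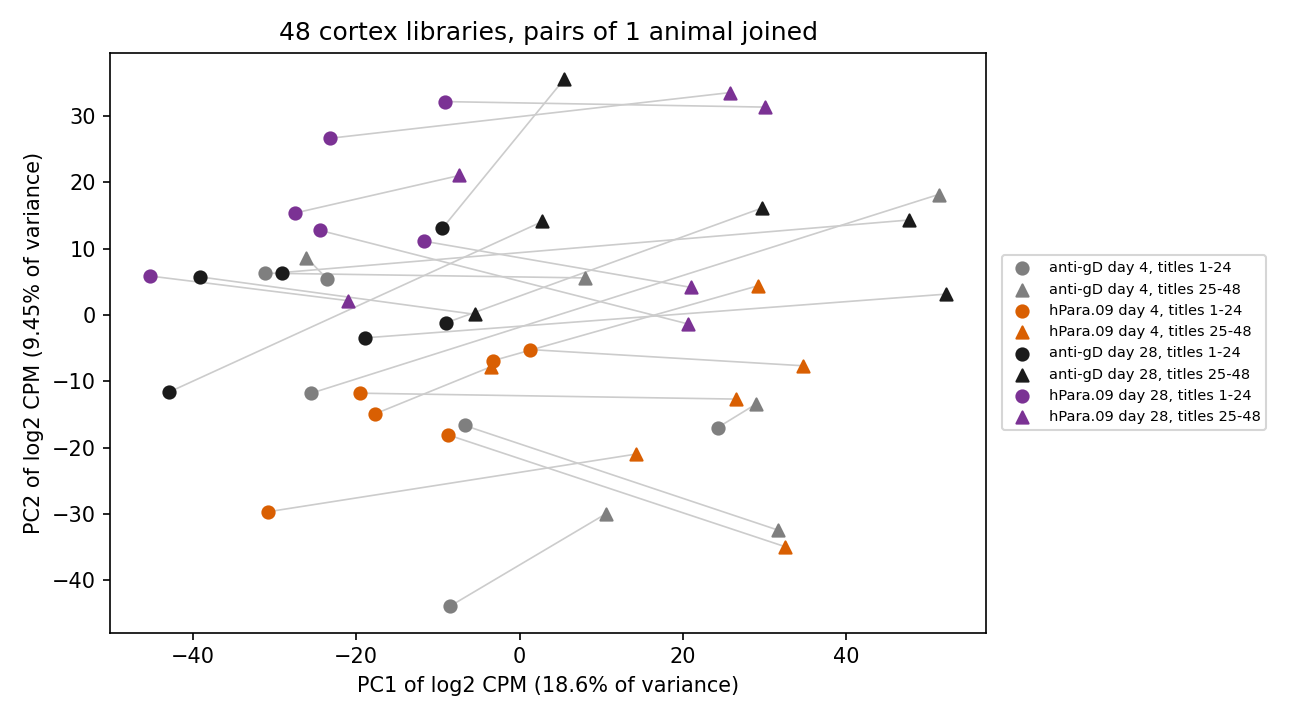
First and second principal components of log2 CPM (x axis, 18.6% of the variance; y axis, 9.45%) for the 48 libraries, coloured by group, with both libraries of an animal joined (circle, title numbers 1 to 24; triangle, 25 to 48). The higher-numbered library lies further right in 23 of 24 animals.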

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

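The test for a single animal far from the rest of its group was run on 64 sets of 6 animals, over library measures and named genes, and 2 passed where chance gives about 1 in 20. ENSMFAG00000000864, the gene with the smallest p at day 4, stood at 15.44 CPM in animal 24 of the hPara.09 day 28 group, with the other 5 animals between 9.451 and 11.37 CPM. ENSMFAG00000041678, the gene with the largest rise between library sets, stood at 219.4 CPM in animal 9 of the hPara.09 day 4 group, with the other 5 between 8.22 and 63.41 CPM.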

How the results depend on the processing

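Alternatives with the exonic share, the set as a term, libraries 29 and 40 left out, the newer edgeR version, thinning, the abundant IDs left out, set means removed, and the contrasts pooled or within hPara.09 animals were chosen after seeing the data. The oligodendrocyte and XIST covariates, the gene list tests and the gene list scores were not run, because no ID had a name. No called named gene reversed in any alternative. The cause was not tested for any change of count below.

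hPara.09 against anti-gD gave 1 gene at day 4 with DESeq2 and with title numbers 1 to 24, and 2 genes at day 28 with DESeq2. The difference between days gave 1 with DESeq2, 1 with limma voom, 1 with the set as a term and 1 with the newer edgeR version. Pooled over days, the antibody gave 1 with DESeq2. All their other alternatives gave 0. Each animal left out gave 0 to 1 at day 4, 0 to 0 at day 28, 0 to 0 for the difference between days and 0 to 1 pooled. The control days gave 57 genes with DESeq2, 16 with title numbers 1 to 24, 1 with limma voom and the set as a term, 1 with the exonic share, and 0 to 3 with each animal left out.

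Day 28 against day 4 in hPara.09 animals gave 44 genes. It gave 28 with upper-quartile factors, 4 with no filter, 550 with DESeq2, 229 with limma voom, 198 with the set as a term and 72 without libraries 29 and 40. It gave 308 with title numbers 1 to 24, and 0 with title numbers 25 to 48, with only the groups compared and with the exonic share. Each animal left out gave 0 to 316. Over both antibodies the 770 genes became 1493 with DESeq2, 1475 with title numbers 1 to 24, 0 with title numbers 25 to 48 and 3 with the exonic share, and 287 to 1376 with each animal left out.

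The library set count of 9359 stayed between 6881, with no replicate block, and 9446 over its 33 alternatives, 8964 to 9446 with each animal left out, and 6875 of the genes called without the block were among the 9359. The share of variance between animals moved from 31.0% to 46.8% with set means removed. At these depths and numbers of animals, 39.7% of simulated 1.5-fold changes were recovered at day 4, so changes of that size may be missed. Depth was not varied in these simulations.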

Other observations

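Of the tests below, those chosen only after the result was seen included gene length and the state of each animal's libraries. They also included the day contrasts outside the anti-gD group, and the splits for counts of called genes other than the library sets. Thinning, the exonic share as a covariate and leaving out the most abundant IDs were chosen after seeing the data. The comparison of ENSMFAG00000046527 with other genes was set in its reported form after a first version had left this gene out.

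Over both antibodies, 770 genes differed between day 28 and day 4 in edgeR's test, 412 higher and 358 lower at day 28. Their median absolute log2 fold change was 0.35. The count was 1475 with title numbers 1 to 24 alone and 0 with title numbers 25 to 48. ENSMFAG00000044175 was at 21.09 ± 1.45 CPM (SD, n = 12) at day 28 and 15.45 ± 1.88 CPM at day 4 (log2 fold change 0.45, standard error 0.0648, adjusted p = 0.00365), with all 12 day 28 animals above the day 4 mean. ENSMFAG00000003341 was at 61.3 ± 3.37 CPM at day 28 and 77.62 ± 7.19 CPM at day 4 (log2 fold change -0.34, standard error 0.0512, adjusted p = 0.00365), with all 12 below. Both were chosen after their values were seen, and over the alternatives their adjusted p reached 0.101 and 0.136. Of 100 relabellings of the day within each antibody, 1, the real one, gave as many genes, and the highest of the others gave 309. Leaving out 1 animal moved the count past 1.5 times for anti-gD day 4 animals 2 (334), 4 (287) and 6 (1376), hPara.09 day 4 animals 10 (354) and 11 (400), anti-gD day 28 animals 16 (449) and 18 (510), and hPara.09 day 28 animals 21 (442) and 23 (468).

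Without the 13 most abundant IDs 782 genes were called, so the calls of this day difference do not rest on those IDs themselves. TMM factors, which trim extreme genes, were used with and without them. The step could thus hardly move the other genes and does not decide whether abundant transcripts play a part. The axis of the library sets is argued against, since the day and set fold changes had an r of -0.0733 across genes. Of 99 relabellings, 28 gave a smaller size, and the highest was 0.508. This r does not address how far the calls depend on 1 set. Title numbers 1 to 24 alone gave 1475 genes and title numbers 25 to 48 gave 0. The exonic share had lower means at day 28 with both antibodies, 60.54% and 59.14% against 62.45% and 61.88% at day 4. This passed with neither antibody after adjustment in tests of 6 animals against 6. It was not tested over the 12 against 12 animals of the pooled contrast. The exonic share stays a candidate explanation that the covariate did not exclude. With it as a covariate 3 genes were called and the median absolute log2 fold change of the 770 genes was 0.28, 80.1% of its value, with a jackknife standard error of 14.6 added after that value was seen. By the rule set before this share was known, a share this high spoke against the exonic share. The rule was then changed to ask this of the share less its standard error, which falls short. The median standard error rose from 0.0888 to 0.115 and 768 genes kept their sign. How far smaller folds and wider errors each account for the lost calls was not tested. Time after dosing and the handling of animals of a day are shared by all animals of that day and were not tested.

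In hPara.09 animals alone 44 genes differed between the days, 30 higher and 14 lower, and 1 of 100 splits gave as many, the highest other giving 1. The count was 0 without animal 10, 11, 20, 21, 23 or 24, 1 without animal 7, 3 without animal 22, 5 without animal 12, 11 without animal 9, 178 without animal 8 and 316 without animal 19. It was also 0 with only the groups compared, with title numbers 25 to 48 and with the exonic share as a covariate. The libraries with title numbers 10, 20, 35, 42 and 48 (animals 10, 20, 11, 18 and 24) are listed last in the series, out of number order. No label says why, and whether they form a batch was not tested. The exonic share differed by -2.738 points between the days in hPara.09 animals (exact permutation p = 0.00866, adjusted p = 0.1385), and it stays open as an explanation here. With it the median absolute log2 fold change of the 44 genes went from 0.516 to 0.409 and the median standard error from 0.106 to 0.124, and all 44 kept their sign. Groups did not overlap for 347 genes (2.08%, where chance gives 0.216%), against 57 in the anti-gD animals. The difference of the day effect between antibodies passed for no gene in edgeR's main test, for 1 gene each in its newer version and DESeq2, and for 1 other in limma voom. Far wider gaps than 44 against 0 arose when the antibody was relabelled at random within day. 1 relabelling gave 1348 genes for the animals labelled hPara.09 and 0 for those labelled anti-gD. Another gave 0 and 1848. The count of 44 against 0 is therefore not shown to come from the antibody.

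The library sets of an animal differed in 9359 genes. Of 40 random exchanges of libraries within animals, 1, the real one, gave as many genes, and the highest other gave 0. Thinning to equal totals left 9283 genes and the exonic share as a covariate left 8690. Depth and exonic share therefore each left the pattern in place. Leaving out the 13 most abundant IDs left 9350, but with TMM factors this step could hardly move the other genes. The Spearman correlation of the fold change with gene width across genes was -0.112, a weak correlation. The cut for judging it was set only after the set difference was seen, so a part played by gene length stays open. A cortical site and a difference in handling or sequencing between the sets may each lie behind the difference between the sets. Neither was tested, as the labels do not say what the sets are.

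ENSMFAG00000046527, on in 7 hPara.09 animals and in 0 anti-gD animals, was compared with other genes that are on (at least 1 CPM) in at least 3 animals and off (under 0.5 CPM) in the rest, by summed counts with factors from all IDs. There were 12 such genes. In 1344 of 100001 relabellings of the antibody within day at least 1 of them was as uneven. Unevenness was measured by Fisher's exact test, with p = 0.00458 for this gene. Those on in 3, 4, 5, 18, 19 or 20 animals cannot reach that p in any relabelling, so the comparison rests on the remaining genes. A first version that asked this of each library found 8 genes and left this one out, at 0.515 and 0.557 CPM in 1 library each of 2 off animals, and was then replaced. The gene was picked from all 16721, where its pooled adjusted p was 0.133 in edgeR, so chance stays open. Mixed-up libraries of an animal are argued against, since in 0 of 24 animals did 1 library lie at 1 CPM or more and the other below it. A hypothesis is that the animals differ by inheritance in this transcript and were unevenly allotted. Samples from before dosing, not analysed here, could help tell this from an effect of the antibody.

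For the planned comparisons, 100 of 100 splits gave as many genes as the 0 called at day 4, at day 28, for the difference between days and for the control days, as any split must, and so did 100 of 100 for the pooled antibody contrast added after seeing the data. The highest others gave 43, 216, 2, 57 and 608 genes, and 7, 3, 5, 9 and 3 of 99 gave any, and whether those with many genes follow a structure of the animals was not tested. At an unadjusted p under 0.05, 93 of 100 splits reached the 433 genes of day 4 (highest other 2931) and 36 of 100 the 809 of day 28 (highest other 3184). The r of -0.0848 between the fold changes of the days was reached in size by 44 of 100 relabellings, the highest other being 0.235.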
